A study of Homo sapiens with 6 samples.

How the data were processed

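RNA from cells labelled as NT2 (NTera-2), an embryonal carcinoma line from a testicular tumour, was sequenced in 6 libraries. According to the sample titles, 3 libraries came from cells given mimics of the piRNA piR-36249 and 3 from cells given a scramble control; a piRNA is a small RNA known mainly from germ cells. The genotype field and the design text speak of a knockdown of piR-36249, while the titles and the treatment field speak of mimics. Samples were grouped by their titles, and every direction below is mimic minus scramble. Per the labels' protocols, total RNA was extracted with TRIzol and a company built and sequenced the libraries. The labels do not say whether the libraries came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

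Per the submitters' processing notes, the tools were Trimmomatic 0.39, HISAT2 2.1.0, featureCounts 2.0.1 and DESeq2 1.26.0, with genome build GRCh38. The annotation release, the counting options, the use of strand and the FPKM formula are not given in the sources used here. The authors deposited a table of FPKM values (values scaled to gene length and library depth) for 58051 Ensembl genes in the 6 libraries, of which 27635 genes were listed at 0 in all of them. The table held 0 columns of other samples. The authors' deposited comparison table held 401 genes with a mean of normalized counts, a log2 fold change and its standard error on the log2 scale, a test statistic (a score) and unadjusted and adjusted p-values, per the file headers. All 401 had an absolute log2 fold change of at least 1.00 and the largest adjusted p-value was 0.0499, so the table is a filtered list. The deposited score had the opposite sign of the deposited log2 fold change in all 401 genes. The sign of the fold change was that of mimic minus scramble FPKM in all 401, and this sign was used.

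Gene names and positions came from GENCODE release 29 on GRCh38 and from a table of gene symbols; 57447 of the 58051 identifiers matched. FPKM multiplied by the union exon length of GENCODE 29 gave whole multiples of a constant step in each library. With a tolerance of 0.02 reads, between 94.6% and 94.7% of the low values per library came out whole. The step corresponds to depths of 58.6, 54.0 and 48.0 M reads in mimic replicates 1 to 3 and 62.7, 52.8 and 53.5 M in scramble replicates 1 to 3. At these depths 10 reads on 1 kb of exon are worth between 0.159 and 0.208 FPKM. The recovered and normalized reads had a median ratio of 0.998 to the mean counts of the authors' deposited table, over the 371 genes that could be compared. Even numbers of reads were in excess: on average 1786 genes per library had exactly 2 reads and 1530 had 1, 904 had 4 and 683.5 had 3, 542 had 6 and 431 had 5, and 368 had 8 and 324 had 7. Whether mates of a pair were counted as separate reads, which would lower the printed depths if given in fragments, was left open.

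FPKM values are not counts, so the test was limma 3.58.1 (R 4.3.3) with a variance trend on log2(FPKM + 1), for the 12912 genes with a mean of at least 0.5 FPKM over all libraries, with Benjamini-Hochberg adjustment at 0.05. The model held the group and no covariate. Fold changes on this scale understate the change of genes with low values. OAS2 and DHX36, the genes in the series title, were also compared with exact permutation tests. Of 27 gene lists fixed before the data were examined, the 23 with at least 4 tested genes were tested with limma's camera, which compares a list with all other genes (preset correlation 0.01, and again with the correlation estimated from the data), and with fry, which asks whether a list's genes moved on balance to one side. Fry does not compare a list with other genes, so lists can pass it widely where many genes change. Adjusted p-values of lists are over the 23 lists.

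Genes named in the text follow a rule fixed before the data were examined. It takes OAS2 and DHX36, then the 10 genes with the largest rise and the 10 with the largest fall among called genes with a symbol that have a mean of at least 1 FPKM in a group and no overlap between the groups' values. It adds the 10 highest and 10 lowest genes of the authors' deposited table with a symbol and such a mean, and up to 4 members of each list with the smallest p. Other genes named were chosen after their values were seen. The model was tested on simulated data for this comparison with 12912 genes. It recovered 77.6% of genes changed by 0.5 on the log2 scale, 94.0% at 1 and 100% at 2, with 5 false calls, 2.69% of the calls. Only 67, 67 and 66 genes were changed at these sizes, picked among genes with higher values, and the noise was independent between genes. In the real comparison 35.5% of tested genes passed, so these rates may not carry over to it.

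Alternatives covered the pseudocount, the filter on low values, the scaling between libraries, the variance model, the replicate number as a block, each library left out in turn, the correlation within lists and a fold change limit. A fit with limma's voom on the recovered reads was added after seeing the data. The search for short sequences in 3′ UTRs, also added after seeing the data, used GENCODE 29 transcripts and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. For each of 10594 tested protein-coding genes the transcript with the longest 3′ UTR (at least 10 bases) was taken, log2 fold changes were corrected for 3′ UTR length and GC content, and each of 16174 sequences of 7 bases carried by at least 50 genes got a score, its mean corrected fold change over the standard error. On shuffled fold changes of the 10594 genes with a planted sequence, the planted sequence ranked 1. Reads, the sequence of piR-36249 and protein levels were not used here.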

Results

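The data set holds 6 RNA-seq libraries, 3 from cells given piR-36249 mimics and 3 from cells given a scramble control. Depth was between 48.0 and 62.7 M recovered reads per library, and each library had between 11138 and 11211 genes above 1 FPKM. Values below are FPKM as the authors computed it, given as mean ± SD of the 3 libraries of a group. Correlations of log2 values across genes were between 0.994 and 0.996 within groups and between 0.985 and 0.988 across groups. The axis with most variance held 63.9% of it and separated the groups.

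The labels name an embryonal carcinoma line, so genes of such cells were read in all 6 libraries before the groups were compared. Of 30 pluripotency genes fixed beforehand, 22 had a mean under 0.5 FPKM and 10 were listed at 0 in every library. Among the latter were NANOG, SOX2, TDGF1, L1TD1 and SALL4, while POU5F1 lay between 0.0332 and 0.0706 FPKM and LIN28A at 0.00945 FPKM at most. LIN28B (12.5 ± 2.0 over the 6 libraries), DPPA2 (5.23 ± 0.76), CD9 and PODXL were present. Of the lists for other cell types, 1 of 20 neuroectoderm genes, 3 of 22 mesoderm and endoderm genes, 2 of 15 trophectoderm genes, 2 of 19 blood genes and 6 of 18 fibroblast genes were above 1 FPKM in all libraries. Several genes known from endothelial cells, picked after their values were seen, were abundant, with CDH5 at 106 ± 20 and TIE1 at 97.9 ± 6.57 FPKM over the 6 libraries. These levels concern every comparison below, since they were found in mimic and scramble libraries alike.

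The series title asks about OAS2, an enzyme that senses double-stranded RNA and activates RNase L, and DHX36, a helicase that unwinds G-quadruplexes. OAS2 (ENSG00000111335, chromosome 12, 112978395 to 113011723, plus strand, GRCh38) rose from 15.6 ± 1.89 FPKM with scramble to 49.9 ± 3.95 with mimic, a ratio of 3.20. Its log2 fold change was 1.62 (SE 0.089, adjusted p = 2.6e-05), and 1.67 in the authors' deposited table. The lowest mimic library (46.5 FPKM) lay above the highest scramble library (17.3 FPKM). DHX36 (ENSG00000174953, chromosome 3, 154272546 to 154324497, minus strand) measured 5.55 ± 0.267 FPKM with mimic and 5.39 ± 0.0971 with scramble, a log2 difference of 0.04 (SE 0.049, adjusted p = 0.585). In exact two-sided permutation tests OAS2 gave p = 0.1, the smallest that 3 against 3 libraries allow, and DHX36 gave p = 0.4. OAS genes are similar in sequence, so reads shared between them could be counted unevenly.

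**Figure D1:**
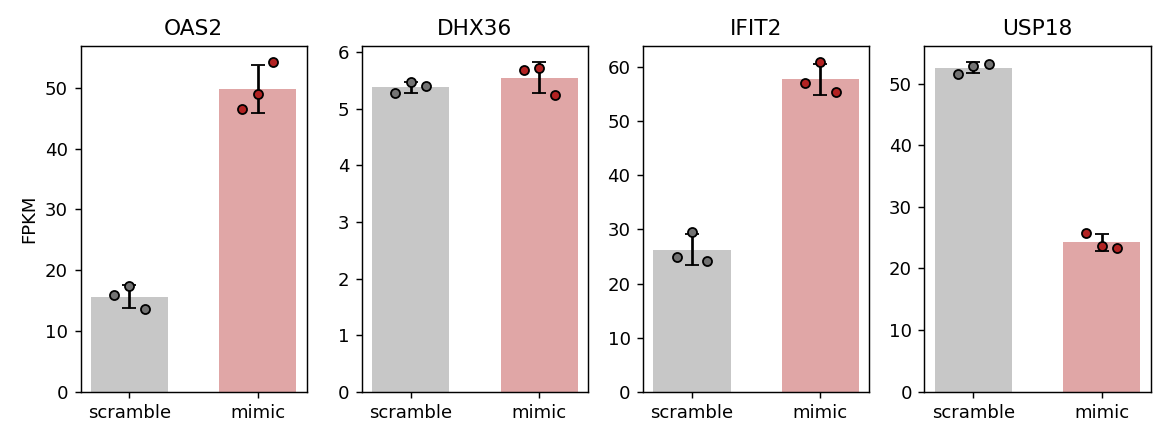
FPKM (vertical axes, starting at 0) of OAS2, DHX36, IFIT2 and USP18 in scramble and mimic libraries; bars are means, error bars SDs and points the 3 libraries of a group. OAS2 and IFIT2 lie higher with mimic, USP18 lower, and the DHX36 values overlap.

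The rise of OAS2 stood among interferon-stimulated genes. Of 49 tested genes of that list, 33 rose, 1 fell and 15 did not pass the test (36 and 2 adjusted over the list alone). IFIT2, which binds viral RNA, rose from 26.2 ± 2.86 to 57.8 ± 2.84 FPKM (log2 1.11), UBE2L6, the conjugating enzyme for ISG15, rose by 0.66 and IFITM1 by 1.11. USP18, the protease that removes ISG15 and dampens interferon signalling, fell from 52.6 ± 0.898 to 24.3 ± 1.37 FPKM (log2 -1.09, adjusted p = 1.1e-05). The list's median log2 fold change was 0.33, with camera adjusted p = 8.4e-10 and adjusted p = 0.255 with an estimated correlation. With fry its adjusted p was 0.0023. IFITM1 has close paralogs, and its value is uncertain for that reason.

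In both lists around RNA sensing more genes rose than fell. In the OAS and RNase L list, which shares genes with the interferon list, 5 of 7 genes rose, with OAS1 up by 0.75 and OASL by 0.61 on the log2 scale, and PDE12, which degrades the second messenger made by OAS enzymes, fell (log2 -0.22); camera gave adjusted p = 0.016 and adjusted p = 0.255 with an estimated correlation. Among 23 RNA sensing genes 10 rose and 3 fell (11 and 3 adjusted over the list alone). IFIH1, the sensor MDA5, rose by 0.69, the kinase JAK1 by 0.57, the adaptor MYD88 by 0.48 and the receptor chain IFNAR1 by 0.40. For this list camera gave adjusted p = 0.017 and adjusted p = 0.355 with an estimated correlation, and the call was lost at a filter of 5 FPKM (adjusted p = 0.183). The fry adjusted p was 0.0020 for the OAS and RNase L list and 0.0046 for the RNA sensing list. NF-kB targets showed no common direction: 3 of 17 rose, among them NFKBIA (0.51) and TNFAIP2 (0.52), and 3 fell, among them IL1B (-0.71), with camera adjusted p = 0.527.

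Among genes closest to DHX36 and to piRNAs, helicases fell in part and most piRNA pathway genes were near 0. The G-quadruplex helicase list also holds CNBP, which is not a helicase, and shares BLM with the S phase list. Of its 9 tested genes 4 fell, DDX21 (-0.56), PIF1 (-0.33), DHX9 (-0.18) and BLM (-0.29), and none rose (camera adjusted p = 0.13, fry 0.026). DHX9 lost its call without mimic replicate 1 or 3 or scramble replicate 1 or 2 (adjusted p up to 0.083) and on the TPM scale (0.071), and BLM without any single library other than mimic replicate 2 (up to 0.080). Of 24 genes of the PIWI and piRNA pathway 18 had a mean under 0.5 FPKM, and the highest library value of PIWIL1 was 0.00646 and of PIWIL2 0.0474 FPKM. Of the 6 tested, TDRD7 rose (0.37) and PLD6 (-0.44) and SPOCD1 (-0.36) fell, while GTSF1 did not pass the test (-0.12), with camera adjusted p = 0.719.

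Across all genes, 4584 of 12912 tested passed the test, 2417 higher and 2167 lower with mimic. Of these, 62 reached 1 on the log2 scale (27 higher, 35 lower), a count that depends on the scale: it was 197 with a pseudocount of 0.1, 229 with 0.01, 134 on the TPM scale and 215 with voom on recovered reads. The order below is that of log2(FPKM + 1), which shrinks the changes of genes with low values. The genes with the largest rise on it were CEACAM1 (1.72, from 7.09 ± 0.657 to 25.6 ± 1.32 FPKM), a cell adhesion receptor, CYP1A1 (1.63, a ratio of 5.71 in FPKM), an enzyme induced through the aryl hydrocarbon receptor, OAS2, and ITGA5 (1.46, from 188.7 ± 4.94 to 521.6 ± 15.2 FPKM), the fibronectin receptor subunit. They were followed by the protease ADAM19 (1.34), PI16 (2.94 times higher in FPKM), KANK3 (1.23), the collagen gene COL5A1 (1.21), SCUBE1 (1.18) and the matrix protease MMP2 (1.17).

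The largest falls on the same scale were in COX7C (-1.61, from 30.1 ± 4.69 to 9.12 ± 0.575 FPKM), a subunit of cytochrome c oxidase, and ERP29 (-1.47, from 47.8 ± 1.79 to 16.7 ± 1.41 FPKM), a chaperone of the endoplasmic reticulum. PTMAP2 (-1.41), WASF3 (-1.41), an actin regulator, ELFN1-AS1 (-1.37) and SLC25A5 (-1.37, from 318.1 ± 12.2 to 122.6 ± 5.57 FPKM), the ADP/ATP carrier, came next. SNHG6 (-1.35) and C9orf78 (-1.24) completed the group, with AATF at 0.393 of its scramble FPKM and KRTAP2-3 at 0.312. PTMAP2 is a processed pseudogene that can take reads of its parent gene, KRTAP2-3 has near-identical copies, and ELFN1-AS1 is named as an antisense RNA, so these values are uncertain.

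The authors' deposited table listed 219 genes as higher and 182 as lower. Of these 401, 209 were above the filter on low values and were refitted; all 209 had the same direction and 205 passed the test. Without the filter all 401 had the same direction and 289 passed. This is not independent evidence, since both come from the same libraries. Among its genes with a symbol and a mean of at least 1 FPKM in a group, the largest rises were SCUBE1 (2.54), CYP1A1 (2.50), CEACAM1 (1.85), KANK3 (1.84) and CBX1P3 (1.76), and the largest falls were LINC00659 (-2.56), MEST (-1.86), ELFN1-AS1 (-1.84), CDC20-DT (-1.73) and COX7C (-1.73), all as log2 fold changes of the authors' deposited table. Further down it gave ACP5 (1.57), CD33 (-1.60) and DYRK3-AS1 (-1.59). CBX1P3 is a pseudogene and LINC00659, CDC20-DT and DYRK3-AS1 are annotated as antisense, which makes them uncertain without strand.

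Most genes of the cell cycle lists fell. Of 34 genes of the G2 and M phases 26 fell and none rose (28 fell adjusted over the list alone), among them UBE2C (-0.95, from 145.4 ± 3.72 to 74.8 ± 1.57 FPKM) and CDC20 (-0.71), both of the anaphase-promoting complex pathway, BIRC5 (-0.71) and the kinase PLK1 (-0.61). Of 30 S phase genes 22 fell and 1 rose (23 and 1 adjusted over the list alone), with RRM2, a subunit of ribonucleotide reductase, at -0.99 (from 60.6 ± 1.13 to 30.02 ± 0.6 FPKM), the helicase subunits MCM7 (-0.52) and MCM6 (-0.37) and the replication factor CDC45 (-0.41). Camera gave adjusted p = 1.3e-11 for the former and 1.8e-07 for the latter, and both had adjusted p = 0.199 with an estimated correlation. With fry the adjusted p was 0.00056 for the G2 and M list and 0.00048 for the S phase list. Replication-dependent histone genes, by contrast, had 5 of 13 higher and none lower, with H2BC5 at 0.68, H2AC6 at 0.55, H4C8 at 0.39 and H2BC11 at 0.25 (camera adjusted p = 0.0079, and adjusted p = 0.199 with an estimated correlation). H2BC11 lost its call without mimic replicate 1 or 2 or scramble replicate 1 (adjusted p up to 0.077) and with the replicate block (0.058). The fry adjusted p of the histone list was 0.0025. Histone copies are near-identical, so single values are uncertain.

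**Figure D2:**
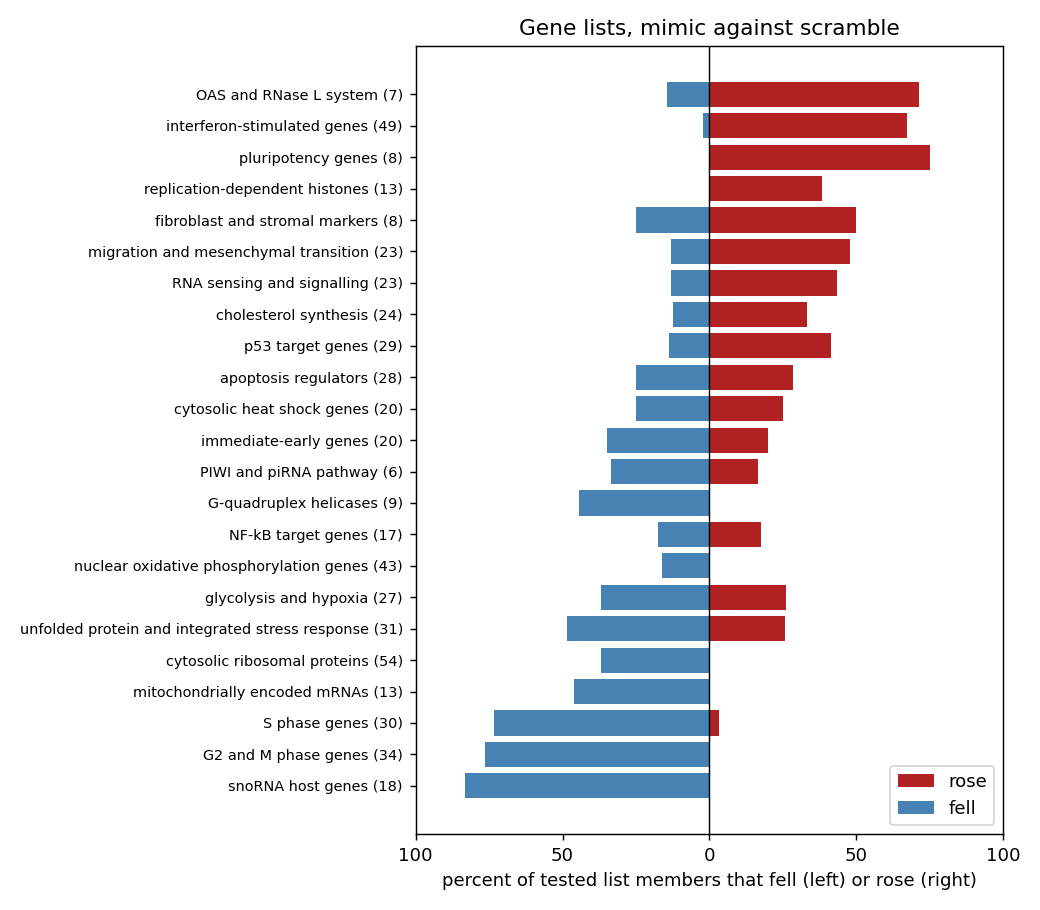
Percent of the tested members of each gene list that rose (right) or fell (left) with mimic, lists ordered by median log2 fold change and the number of tested genes in brackets. Interferon-stimulated genes lie far to the right (33 of 49 rose) and G2 and M phase genes far to the left (26 of 34 fell).

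Among genes of ribosome production more fell than rose. Of 18 snoRNA host genes, non-coding genes whose introns hold snoRNAs, 15 fell and none rose, with SNHG6 at -1.35, SNHG16 at -0.79, DANCR at -0.74 and SNHG15 at -0.44 (camera adjusted p = 1.8e-07, and adjusted p = 0.226 with an estimated correlation, fry 0.0020). Of 54 cytosolic ribosomal protein genes 20 fell and none rose (21 adjusted over the list alone), with small sizes in RPL15 (-0.27), RPL7A (-0.27), RPS3 (-0.34) and RPS3A (-0.25). Camera gave adjusted p = 2.8e-07 for them, adjusted p = 0.506 with an estimated correlation and fry 0.081. Ribosomal protein genes have many pseudogenes that can share their reads.

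Of 13 mitochondrially encoded mRNAs 6 fell, among them MT-ND6 (-0.28), MT-ATP6 (-0.33), MT-ATP8 (-0.82) and MT-CYB (-0.28), with camera adjusted p = 0.017 and adjusted p = 0.446 with an estimated correlation. MT-ATP8 overlaps MT-ATP6, and the camera call was lost after quantile normalization (adjusted p = 0.131). The fry adjusted p of this list was 0.024. Nuclear genes of oxidative phosphorylation had 7 of 43 lower and none higher (6 adjusted over the list alone), beside 2167 lower among all 12912 tested genes, led by COX7C, the ATP synthase subunit ATP5F1B (-0.80), SDHA (-0.40) and COX8A (-0.23). Their camera adjusted p was 0.0040, but it was 0.573 with an estimated correlation and 0.075 without scramble replicate 3, and fry gave 0.081.

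Among stress and metabolic lists, 15 of 31 genes of the unfolded protein and integrated stress response fell and 8 rose (18 and 8 adjusted over the list alone). MTHFD2 (-0.93), ATF5 (-0.67) and PHGDH (-0.56), of amino acid and folate metabolism and their regulation, fell, whereas the chaperone HSPA5 rose (0.65, from 368.1 ± 8.95 to 576.3 ± 17.9 FPKM). Camera gave adjusted p = 0.022, lower, and adjusted p = 0.199 with an estimated correlation, and fry gave 0.00056, lower. Of 24 cholesterol synthesis genes 8 rose and 3 fell (9 and 3 adjusted over the list alone), with INSIG1 at 0.64 and PMVK at -0.51. Camera gave adjusted p = 0.022 and adjusted p = 0.199 with an estimated correlation, and the call was lost at a filter of 5 FPKM (0.052) and with voom on recovered reads (0.24). With fry the adjusted p of this list was 0.00048. In the glycolysis and hypoxia list 7 of 27 rose and 10 fell (8 and 11 adjusted over the list alone), with NDRG1 at 0.73, HK2 at -0.67, BNIP3 at -0.38 and BNIP3L at -0.26 (camera adjusted p = 0.13, fry 0.0045). Of 20 heat shock genes 5 rose and 5 fell (6 and 5 adjusted over the list alone), with DNAJB1 at -0.72, DNAJB4 at 0.36, and the near-identical HSPA1A at 0.34 and HSPA1B at 0.30. The camera adjusted p was 0.876, and camera and fry gave opposite directions.

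The migration and mesenchymal transition list had 11 of 23 genes higher and 3 lower (12 and 3 adjusted over the list alone). ITGA5 led it, followed by MMP2 (1.17) and the matrix protein SPARC (1.15, from 39.7 ± 0.623 to 89.2 ± 2.77 FPKM). The 3 that fell, named after their values were seen, were PLAU (-0.66), PLAUR (-0.43) and MMP1 (-0.42), which act in plasminogen activation and collagen breakdown. Camera gave adjusted p = 0.022 and adjusted p = 0.255 with an estimated correlation, and fry gave 0.00056. The list as fixed mixes epithelial and mesenchymal genes, so a common direction cannot be read as a mesenchymal transition. In the fibroblast list 4 of 8 rose, among them COL5A1 (1.21), THY1 (0.31) and FBN1 (0.29), and 2 fell, among them LOX (-0.45), with camera adjusted p = 0.349 and fry 0.0023.

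Among p53 targets 12 of 29 rose and 4 fell (12 and 5 adjusted over the list alone), with TP53INP1 at 0.82, SESN1 at 0.51, AEN at -0.55 and EDA2R at -0.47 (camera adjusted p = 0.111, fry 0.0034). Apoptosis regulators went both ways, 8 of 28 higher and 7 lower, with BAK1 at 0.66, CFLAR at 0.37 and BCL2A1 at -0.76 (camera adjusted p = 0.502, fry 0.020). Of 20 immediate-early genes 4 rose and 7 fell, with KLF2 at 0.81, CCN2 at -0.45, SRF at -0.37 and MYC at -0.35. Their median log2 fold change was 0.0071 and their mean 0.042, while camera pointed down with adjusted p = 0.502.

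Of the 8 pluripotency genes that could be tested 6 rose and none fell, among them CD9 (0.45), DNMT3B (0.58), KLF4 (0.51) and LIN28B (0.33), with camera adjusted p = 0.0084 and adjusted p = 0.199 with an estimated correlation. The fry adjusted p was 0.00056. CD9 and KLF4 are used by many cell types. The lists with fewer than 4 tested genes were not tested as lists. In them FOXF1 (0.46), SOX17 (0.34), GATA3 (0.34), CORO1A (0.49) and LAPTM5 (0.20) rose, SOX17 losing its call without mimic replicate 1 or 3 or scramble replicate 1 or 2 (adjusted p up to 0.095). GATA6 (0.11), GATA2 (0.02), KRT7 (-0.02), LHX2 (0.07), NES (-0.05) and TUBB3 (-0.06) did not pass the test. In every list not given with a count adjusted over the list alone, that count equalled the one over all genes.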

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

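Counts of genes and lists, the refit of the authors' deposited genes and the named genes were recomputed under the alternatives that kept them in the test; marker levels, permutation tests and the search for short sequences were not. Of the alternatives, voom on recovered reads was chosen after seeing the data. Between 3290 and 5362 genes passed the test under the other filters, pseudocounts, scalings, models and with single libraries left out, against 4584; leaving out 1 library gave 3387 to 3998, and voom on recovered reads gave 4587. With a change of at least 1 on the log2 scale required, 62 passed, against 197 with a pseudocount of 0.1, 229 with 0.01, 134 on the TPM scale, 215 with voom on recovered reads and 44 to 77 under the other alternatives; a pseudocount of 1 shrinks the changes of genes with low values. The log2 fold change of OAS2 stayed past the threshold, between 1.53 and 1.69, and that of DHX36 stayed short of it, between 0.02 and 0.07. Camera called 14 lists and fry 17, and alternatives that kept the preset correlation gave 12 to 16 with camera and 14 to 20 with fry. With the correlation estimated from the data camera called 0, so its calls depend on that setting. The pluripotency (-0.061), cholesterol (-0.029) and unfolded protein (-0.022) lists lost their calls although their estimates lay below the preset 0.01. For these lists a larger correlation is not the reason. The histone list lost its call too, with an estimate of 0.017, just above the preset. The settings of camera also differ in the degrees of freedom behind their p-values. Loss of a call can therefore not be put down to correlation for any list, and the parts of the setting were not tested apart. Of the authors' deposited genes 205 of 209 refitted passed the test, 289 of 401 without the filter and 63 of 63 with a mean of at least 5 FPKM. The other named genes gave 2279 pairs of gene and alternative, of which 2245 kept direction and side of the threshold and 29 lost the call, 11 of them without a filter on low values (DHX9, BLM, LIN28B, SOX17, FBN1, MT-ND6, MT-ATP6, MT-ATP8, MT-CYB, H4C8 and H2BC11). In 5 the sign turned, each for a gene without a call: GATA2 with array weights (-0.00624), and KRT7 on the TPM scale (0.00298), after quantile normalization (0.052), with array weights (0.018) and without scramble replicate 3 (0.049); the cause was not tested. Deviations of samples with the same replicate number correlated at -0.062, 0.24 and 0.054, and those with different numbers at -0.27 to 0.23. Deviations from a group mean depend on each other, so these values cannot settle whether the numbers pair the samples. The replicate block gave 4609 genes. Genes under 0.5 FPKM were tested only without the filter; at the depths here 10 reads on 1 kb of exon are worth 0.159 to 0.208 FPKM, so low values rest on few reads.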

Other observations

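The tests of explanations below were chosen after the result was seen, except the counts of lists over other splits of the libraries, while fold changes and calls of genes come from the planned fit. Some further gene groups were put together after their values were seen and were not tested as groups. Of 10 tested integrin subunits 9 rose and none fell. Beside ITGA5 these included ITGB5 (1.10, adjusted p = 1.7e-05) and ITGB4 (1.06, adjusted p = 1.0e-05), in limma with Benjamini-Hochberg adjustment. Of 18 tested endothelial genes 14 rose and none fell, with a median log2 fold change of 0.34; PLVAP (1.02), PCDH12 (0.94), MMRN2 (0.87) and TEK (0.64) rose most. Of 5 tested targets of the aryl hydrocarbon receptor, with a median log2 fold change of -0.04, CYP1A1 (1.63) and NQO1 (0.41) rose, while AHRR (-0.04) and TIPARP (-0.12) did not pass the test.

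The 30 pluripotency genes had a median of 0.00443 FPKM in the library where it was highest. Reads lost to pseudogenes are argued against by 15 of the 22 list genes under 0.5 FPKM that have no named pseudogene in the annotation. The 10 list genes at 0 in all 6 libraries, SOX2 and L1TD1 among them, argue against an appreciable share of cells that express those genes. A mixture of embryonal carcinoma cells with other cells stays open only for cells that lack these genes or a share too small to show. The level the genes have in the named line was not measured here. LIN28B, DPPA2 and DNMT3B were above 1 FPKM in all 6 libraries. Of 25 endothelial markers 18 were above 1 FPKM in all 6 libraries, with ENG (540 ± 117 FPKM), EGFL7 (281 ± 38.9) and ESAM (141 ± 6.71) most abundant and VWF (0.434), CLDN5 (0.11) and KDR (0.0192) low; SOX17 is also in the mesoderm and endoderm list. Cells of another type than labelled are a candidate explanation that these 18 genes cannot settle, because the list was written after the levels were seen and no profile of the named line was used here.

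A short sequence in 3′ UTRs was more frequent among the genes that fell, though most of them lacked it. GAGCATT, carried by 1106 of 10594 genes (10.4%) and by 372 of the 1830 searched genes that fell, had a score of -20.3, and it was found in 64 of the 100 genes with the largest falls and 2 of the 100 with the largest rises; the lowest score of any sequence in 100 permutations of the fold changes was -4.82, and AGTGGTA (-7.20), AAGTGGT (-6.07) and CAGTGGT (-5.86), which do not contain GAGCATT, lay below it too. Base composition as the whole cause is argued against by the lowest score among 619 sequences of the same bases, -5.04, though it too lay below -4.82. These 619 were limited to sequences that share no long run of bases with GAGCATT. Selection from many sequences is argued against by a score of -12.7 in the 4873 genes not used to find it. Among those genes 160 of 537 carriers and 667 of 4336 others fell (Fisher's exact test, two-sided, p = 4.1e-15). The median log2 fold change was -0.16 for carriers with an A after the sequence (n = 213 genes) and -0.06 for the other carriers (n = 893 genes; Mann-Whitney test, two-sided, p = 8.7e-05). Seed-type pairing of a small RNA could give this difference, as a hypothesis. These fold changes were not corrected for 3′ UTR length, GC content or copies of the sequence. The median was -0.06 with 1 copy, -0.14 with 2 and -0.19 with 3 or more. An effect of the A was therefore not told apart from one of copy number, and other following bases were not compared. Whether piR-36249 or another RNA would pair was not tested. Genes with 6 of the 7 bases (median 0.03) were not lower than genes with none of these matches (0.03); of the 10 genes with the largest falls 7 were searched, and COX7C, SLC25A5, AATF and C9orf78 carry the sequence and ERP29, WASF3 and KRTAP2-3 do not, INSIG1 and THY1 carry it and rose, and while 1 of 34 genes of the G2 and M phases has it, 25 of the other 33 fell.

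Of 49 tested interferon-stimulated genes 33 rose, OAS2 among them. Camera with its preset correlation (adjusted p = 8.4e-10) and fry (0.0023) called the list, though camera did not with an estimated correlation (0.255). Reads shared between OAS paralogs are argued against as the whole cause of the list's rise by a median log2 fold change of 0.30 over the 45 members outside that family. These members cannot tell whether shared reads enlarge the change of OAS2 itself, which was not tested. USP18 restrains interferon signalling. A direct effect of GAGCATT on its mRNA is argued against by 0 copies of the sequence in the USP18 transcript searched (1 transcript). An indirect fall through other carriers of the sequence was not tested, nor was a part of the USP18 fall in the rise of the list. A response to the introduced RNA itself and an effect of its sequence may both give such a rise; with a single mimic and a single scramble they were not tested apart, and both stay open.

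The 6 libraries can be split into equal groups in 10 ways, too few for a share under 0.05. The real split gave 4584 genes in limma, 2417 higher and 2167 lower, and the highest of the other splits gave 0, with up to 738 at an unadjusted p under 0.05. In each case 1 split, the real one, gave as many. Fry gave 17 lists with the real split and 0 at most with another. Camera gave 14 lists with the real split and up to 8 with another, in groups that mix mimic and scramble libraries. Every other split is unequal in mimic and scramble libraries. It therefore keeps part of their difference and adds the rest to the spread within groups. For that reason the splits do not show how many genes or lists would be called without a difference.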
